A study of Mus musculus with 16 samples.

How the data were processed

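The study hybridised 16 RNA samples to Illumina Mouse Ref-8 v1.1 BeadChips, which carry 1 colour of signal per array. Per the labels, 12 samples were individual animals, 6 SR-uPA+/0 transgenic and 6 nontransgenic, and 4 were repeat hybridisations of 2 pools, 1 for each genotype. All mice were Apoe-/- and female and ate a Western diet from 5 to 15 weeks of age, and per the labels' protocols the RNA integrity numbers lay between 8.9 and 9.7. The design text names 2 chips but not which array lay on which, so neither chip nor position could be used as a term and the chip cannot be ruled out as a source of differences.

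The values used were the authors' deposited intensities, on a linear scale, made with BeadStudio per the submitters' processing notes (version not given in the sources used here). Every deposited column of intensity runs below 0 and all columns share nearly the same quartiles, so the authors had subtracted a background and normalized the arrays, by methods not given in the sources used here. A second deposited table holds 16 intensity and 16 detection columns without normalization. Its columns carry only running numbers that match no sample's labels, so these 32 columns were not used. The detection p-values and negative controls that the planned procedure called for were therefore not used here, and a noise limit was taken from the deposited values instead. It was 1.64 times the root mean square of the values below 0 on each array. A probe was tested if it exceeded that limit on at least 3 of the 12 animal arrays, which kept 10521 of 24607 probes after 4 control probes were left out. Depth has no counterpart here beyond signal over noise, and the number of arrays limits the precision.

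Probe names came from the platform annotation given with the values, which can be old. Of the 24607 probes 19851 had 1 gene symbol and 4756 had none here, and 8891 tested probes with a symbol stood for 7499 genes. Where a gene had several tested probes, the brightest stood for it, and other probes are mentioned where their sign or call differs. Older symbols in the gene lists were matched through unique synonyms in a RefSeq gene table of assembly GRCm38.p6, used only for names and neighbouring genes.

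The deposited intensities were passed through limma's normexp background step (saddle method, offset 16), which in effect added 96.98 to every value, and then quantile normalized over the 12 animals and put on the log2 scale. Pool arrays were mapped to the same distribution. Folds of dim genes are understated on this scale. This way of handling values that were already corrected, and the noise limit, were settled after the values had been looked at and several scales had been tried. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Beside limma's test, single values per array were compared with exact two-sided permutation tests over all assignments of the 12 animals, whose smallest p is 0.00216. Where all arrays of a genotype lay below the noise limit, the fold is given as a lower bound against the lowest normalized value above that limit on each array.

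The 27 gene lists, of pathways, of responses to cell handling and of cell types, were fixed before the data were examined and tested with camera (preset correlation 0.01, at least 5 tested members), with camera using an estimated correlation, and with fry. The rule for the genes named was also fixed then, with Plaur, S100a8 and S100a9 included because they belong to the field of this study. It takes Plau, Plaur, S100a8 and S100a9 always, up to 12 genes with the largest change in each direction among those past the threshold, and from each list up to 4 members past the threshold or, where none passed, the 2 with the smallest p. Genes named beyond it, such as Gas6, Ltf, Camp, Lcn2, Csf3r, Chil1, Anxa1, Dcn, Msln, Krt7, Krt8, Krt18, Upk3b, Wt1, Retnla, Arg1 and Fcrls, were chosen after their values were seen. Probes detected, median intensity, the first principal component and the means of the cell type lists made up 12 checks between genotypes.

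The procedure was tested on simulated arrays built from the animal comparison, with 10827 probes past the filter. It recovered 55.2% of 67 probes changed 1.5-fold, 98.5% of 67 changed 2-fold and 97.0% of 66 changed 4-fold. Of the 179 probes it called 167 were among these, 5 belonged to a gene list of 17 probes raised as a whole and 7 had not been changed. The simulated probes were drawn independently, without correlation between genes or structure among arrays, so these numbers need not hold for the real arrays.

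Alternatives fixed in advance covered the background step, the offset, median scaling, cyclic loess, normalization over all 16 arrays, no filter and a stricter filter or limit, eBayes with trend and robust, array weights (statmod 1.5.0), an exact Mann-Whitney test, leaving out each animal, and other set tests. Alternatives added after seeing the data raised dim values to the noise limit, added a larger constant before taking logs, skipped further normalization, and took the number in each animal's title as a term. Others dealt with structure seen in the data. The first principal component of the deviations from the genotype means, 22.0% of their variance, was split at 0 into a first set of 5 arrays (2 transgenic, 3 nontransgenic) and a second of 7. The first set held nontransgenic 1, 2 and 3 and transgenic 1 and 3. Animals are numbered here in the order the series lists them, so apart from transgenic 2 the sets follow that order. Whether they reflect the chips or another batch cannot be told from the sources used here. That split is loose, since transgenic 3 (score 3.64) and transgenic 6 (-2.61) lie near 0, and a split that takes the 4 highest scores was also used. The set was taken as a term in both forms, the first set was left out, transgenic 1 and transgenic 6 were left out, and the neutrophil and fibroblast marker means were taken as terms. Refits for other splits of the animals used 100 of 462 possible splits.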

Results

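RNA of peritoneal macrophages was profiled on 16 hybridisations of Illumina Mouse Ref-8 v1.1 BeadChips. The cells came from female Apoe-/- mice, which lack apolipoprotein E and develop high plasma cholesterol, and which ate a Western diet for 10 weeks, up to 15 weeks of age. Macrophages were drawn into the peritoneum with thioglycollate, collected 5 days later and kept after 2 h of adhesion to plastic. By their labels, 6 of the animals carried a macrophage-directed transgene (SR-uPA+/0) meant to overexpress urokinase plasminogen activator (uPA, encoded by Plau), the protease that turns plasminogen into plasmin. The other 6 were nontransgenic. A pool of the RNA of each genotype was hybridised 2 times, which gave 4 further arrays. Between 9531 and 9544 of 24607 probes lay above the noise limit on each array. That near equality comes from the authors' normalization, so these numbers carry no information on array quality. The number of arrays, 6 per genotype, limits the precision of every comparison.

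Plau, which the transgene should raise, was measured first as a check of the genotype labels. Its only probe read 1660 ± 972 intensity units (SD, n = 6) in the animals labelled transgenic and 1825 ± 1103 (SD, n = 6) in those labelled nontransgenic. The log2 difference was -0.10 (SE 0.42, 95% interval -0.99 to 0.79; limma adjusted p = 0.967; exact permutation p = 0.848). Animals of each label covered nearly the same range, 536 to 2907 in transgenic and 513 to 3527 in nontransgenic. The pools read 3425 and 2586 for transgenic and 3225 and 3424 for nontransgenic. Each of these readings lay above the mean of the animals whose RNA the pool held. The cause was not tested, and it leaves the level of Plau in single animals less certain. The sign of the difference turned when nontransgenic 2 (0.13), nontransgenic 6 (0.02), transgenic 2 (0.15) or transgenic 5 (0.02) was left out. Plau therefore did not separate the labels. Where the probe lies relative to the sequence the transgene carries is not given in the sources used here, so a probe outside it would check nothing. Every direction below refers to the genotype on the label.

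Plaur, the cell-surface receptor of uPA, had a log2 difference of -0.36 (SE 0.17; limma adjusted p = 0.579; exact permutation p = 0.0714, n = 6 per genotype). In the plasminogen activation list, 2 of 21 measured members fell in animals labelled transgenic and 19 did not pass. The same 2 passed when adjusted over the list alone. Plat, the tissue-type plasminogen activator, fell by 1.31 on the log2 scale (SE 0.25; adjusted p = 0.0184). F2r, the thrombin receptor PAR1, fell by 1.22 (SE 0.23; adjusted p = 0.0161). Without nontransgenic 2 neither passed, with adjusted p of 0.0585 for Plat and 0.0551 for F2r. Plat had -1.22 (adjusted p = 0.0777) without the 2 arrays that stand apart, -1.17 (0.487) without a first set of 5 arrays and -0.63 (0.789) with neutrophil and fibroblast marker means as terms. F2r had -0.75 (adjusted p = 0.274) without that set and -1.47 (0.473) with those terms. These fits are described below, and fibroblast markers were lower on the same arrays (mean difference -0.67). The list as a whole did not pass the camera test (mean -0.17; adjusted p = 0.119).

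**Figure D1:**
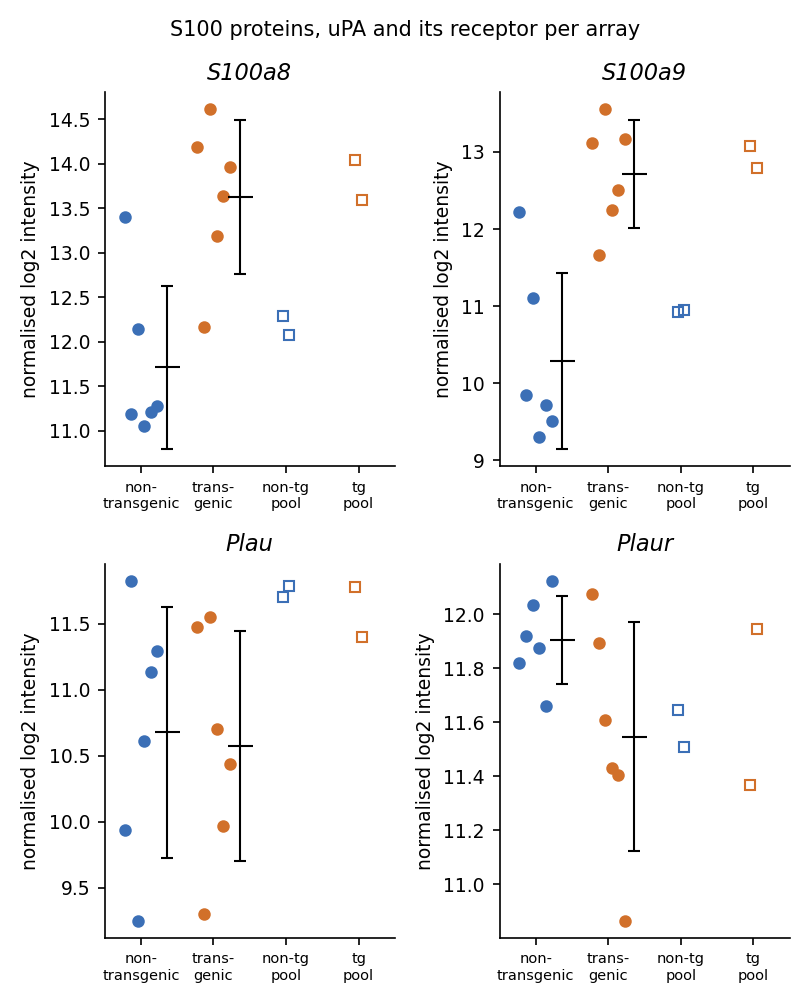
Normalized log2 intensity of S100a8, S100a9, Plau and Plaur per array, by genotype label. Animals are filled dots, repeat hybridisations of the pools open squares, and bars give the mean ± SD of 6 animals. On this log2 scale S100a9 averaged 12.71 in labelled transgenic and 10.29 in labelled nontransgenic animals, while the Plau values of the genotypes overlapped.

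The main comparison asked which transcripts differ between macrophages with and without the uPA transgene. The largest increase was that of S100a9, which with S100a8 forms calprotectin, an inflammatory calcium-binding protein abundant in neutrophils and monocytes. On the normalized log2 scale S100a9 rose 5.37-fold in animals labelled transgenic (log2 change 2.42, SE 0.44, limma adjusted p = 0.0126). Its deposited intensities averaged 1590 ± 1621 units in labelled nontransgenic and 7280 ± 3315 in labelled transgenic animals (SD, n = 6). The fold does not come from these averages. S100a8 rose 3.77-fold (log2 change 1.92, SE 0.41; adjusted p = 0.0388). On the log2 scale used here the largest decreases were those of Cog2, a subunit of a Golgi tethering complex, by 1.72, and Serpinh1, by 1.71. Cog2 lay above the noise limit on only 1 of the 6 arrays labelled transgenic, so its size and rank depend on the constant added before taking logs. So do the sizes given for Plat (above the limit on 1 of 6), F2r (2), Ltbp2 (3) and Mmp23 (3). In all, 77 of 10521 tested probes passed, 11 higher and 66 lower, which stand for 10 and 56 named genes. At an unadjusted p under 0.05 there were 898 probes, 424 higher and 474 lower, where chance would give 526.

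The other genes that rose included several known from neutrophils. Retnlg, a resistin-like secreted protein, rose by 1.42 on the log2 scale (SE 0.23; adjusted p = 0.00622). Pglyrp1, a peptidoglycan recognition protein of neutrophil granules, rose by 1.24 (SE 0.21; adjusted p = 0.00967). Asprv1, an aspartic protease, rose by 2.05 (SE 0.38; adjusted p = 0.0137). Hcar2, the niacin and beta-hydroxybutyrate receptor, rose by 1.58 (SE 0.34; adjusted p = 0.0399). The macrophage lectin Mgl2 rose by 0.86 (SE 0.16; adjusted p = 0.0126), the fractalkine receptor Cx3cr1 by 0.78 (SE 0.16; adjusted p = 0.0263) and the stress-induced Gadd45b by 0.65 (SE 0.14; adjusted p = 0.0399). Each of these genes exceeded the nontransgenic mean in 6 of 6 labelled transgenic animals. They were picked for passing as higher in the same animals, so that count adds no support. A second Mgl2 probe had a value of 0.63 (adjusted p = 0.165). Dlg1, a membrane scaffold protein, rose by 1.53 on 1 probe (SE 0.17; adjusted p = 1.84e-04), whereas its other tested probe had -0.09 (adjusted p = 0.911). The first probe was above the noise limit on only 1 of the 6 arrays labelled nontransgenic, so the size of this change depends on the added constant.

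Several of the genes that fell belong to the extracellular matrix, a grouping made after the calls were seen and not tested as a set. Mesothelial and fibroblast markers were lower on the same arrays (mean difference -0.67). With marker means as terms, described below, the changes of Serpinh1, Col6a1, Col1a1, Ltbp2, Loxl1, Serpinf1 and Igfbp4 were smaller and did not pass. Col6a1 and Col1a1 are members of the fibroblast marker mean, so their smaller changes in that fit follow in part from construction. Col5a1 had -1.93 there and passed. Serpinh1, the collagen chaperone HSP47, fell by 1.71 on the log2 scale (SE 0.25; adjusted p = 0.00215) and Col5a1 by 1.61 (SE 0.16; adjusted p = 6.21e-05). Col6a1 was 2.83-fold lower. Col1a1 fell by 1.41, the latent TGF-beta binding protein gene Ltbp2 by 1.51 and the matrix cross-linking enzyme gene Loxl1 by 1.39, with adjusted p between 0.00261 and 0.0267. Serpinf1, which encodes the secreted factor PEDF, fell by 1.46 and the growth factor binding protein gene Igfbp4 by 1.36. The second Igfbp4 probe had a value of -0.84 (adjusted p = 0.161). Outside the matrix genes, Pebp1, an inhibitor of Raf kinase, fell by 1.63 on the normalized log2 scale (SE 0.11, adjusted p = 1.12e-06). Its deposited intensities averaged 877 ± 118 units in labelled nontransgenic and 216 ± 30.9 in labelled transgenic animals (SD, n = 6). Med30, a Mediator subunit, fell by 1.61 (SE 0.14; adjusted p = 2.50e-05) and Relb, a transcription factor of the noncanonical NF-kappaB pathway, fell by 1.49 (SE 0.17; adjusted p = 2.14e-04).

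For 113 probes, 36 higher and 77 lower, the values of the genotypes did not overlap, where chance would give 22.8 on average (0.216%). Splits of the animals spread widely around that average. Among probes above the noise limit on all 12 arrays, genotype separated 64 and another split 103. Of the 113 probes, 61 passed the limma test. Pebp1, Med30, Cog2, Relb, Col5a1 and Dlg1 were among them.

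**Figure D2:**
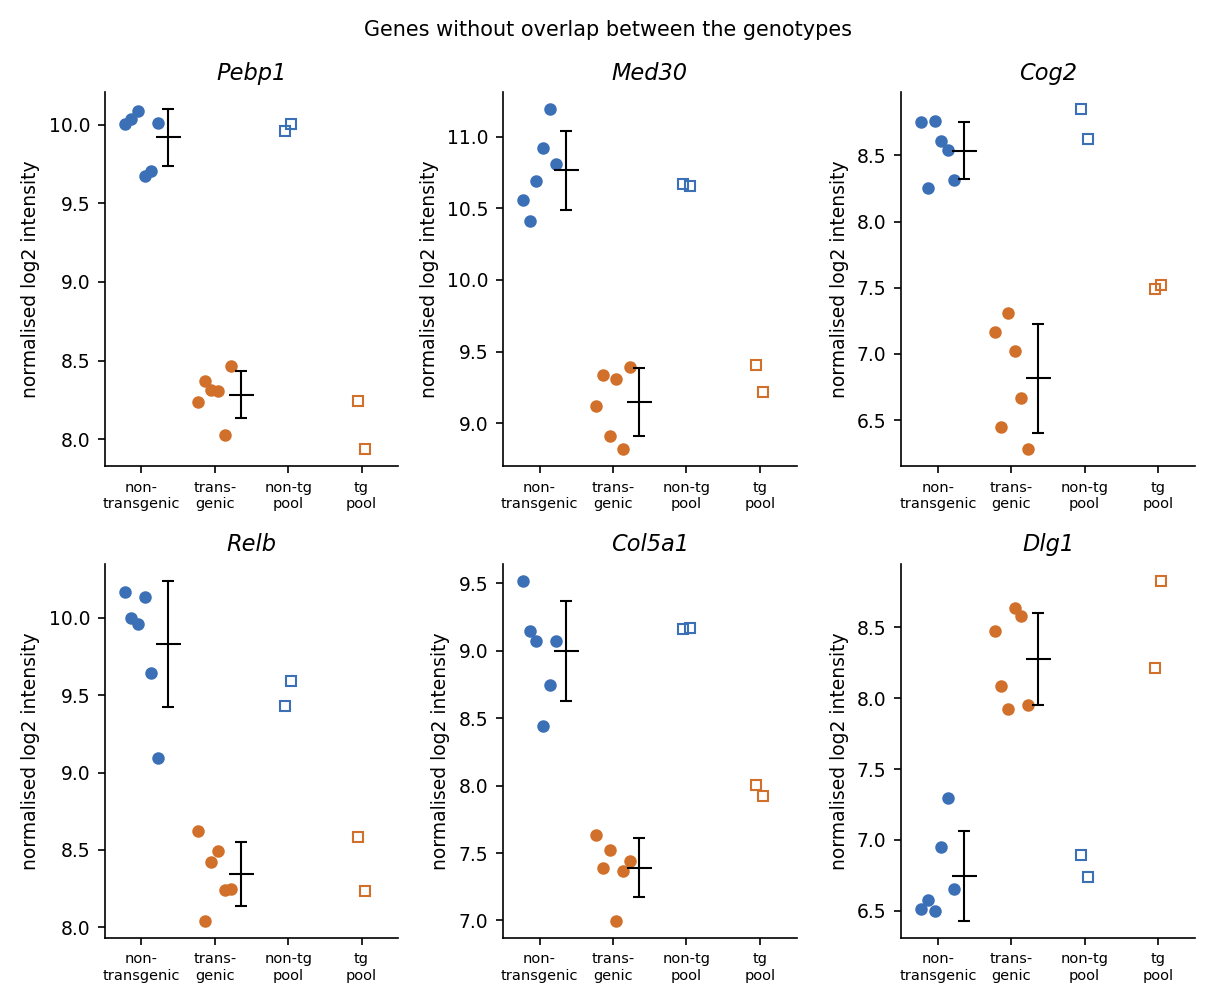
Normalized log2 intensity per array of Pebp1, Med30, Cog2, Relb, Col5a1 and Dlg1. Animals are filled dots, pool repeats open squares, and bars give the mean ± SD of 6 animals. No labelled transgenic animal overlapped a labelled nontransgenic animal for any of these 6 genes.

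Single animals moved these counts. The number of higher probes was 6 without nontransgenic 6, transgenic 4 or transgenic 5 and 7 without nontransgenic 2, nontransgenic 3 or transgenic 3, and the number of lower probes was 34 without nontransgenic 2 and 39 without transgenic 4. S100a8 lost its call in 10 of 12 such fits, with adjusted p up to 0.119 without nontransgenic 2, and kept it only without nontransgenic 1 or transgenic 2. S100a9 kept its call in all 12. Hcar2 lost its call in 9 (up to 0.121) and Gadd45b in 10 (up to 0.121), each highest without nontransgenic 2, and Cx3cr1 in 5 (up to 0.0710, without transgenic 4). Ltbp2 lost its call in 5 (up to 0.0861, without nontransgenic 2) and Col6a1 in 2, without nontransgenic 2 (0.0585) or transgenic 4 (0.0538).

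Choices of processing ended calls of named genes too. Without a filter on dim probes these were S100a8 (adjusted p = 0.113), Hcar2 (0.119), Cx3cr1 (0.0919), Gadd45b (0.129), Ltbp2 (0.0865), Col6a1 (0.0631), Plat (0.0631), F2r (0.0551), Timp3 (0.0762), Vegfc (0.117), Egfr (0.0691), Col3a1 (0.0609) and Serping1 (0.0691). With only probes above noise on all 12 arrays they were S100a8 (0.0573), Hcar2 (0.0584) and Gadd45b (0.0573), and with eBayes trend and robust S100a8 (0.0871), Hcar2 (0.0875) and Ltbp2 (0.0597). With dim values raised to the noise limit S100a8 (0.0808), Hcar2 (0.0808), Gadd45b (0.0565), Col6a1 (0.0534), Egfr (0.147) and Col3a1 (0.198) lost their calls. Cx3cr1 (1.27), Col5a1 (-2.45), Mmp23 (-1.46) and Vegfc (-1.32) passed there with larger changes. No gene passed the exact Mann-Whitney test.

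Transcripts of other cell types moved with the genotype label. The mean of 14 neutrophil markers was higher by 0.84 on the log2 scale in animals labelled transgenic (exact permutation p = 0.00433, adjusted p = 0.0260 over 12 checks), and the mean of 15 mesothelial and fibroblast markers differed by -0.67 (exact permutation p = 0.00216, the smallest that 6 against 6 animals can give; adjusted p = 0.0260). S100a8, S100a9, Retnlg and Pglyrp1 are themselves among the neutrophil markers, and the collagen genes Col1a1, Col3a1 and Col6a1 among the fibroblast markers. The mean of 8 B cell markers differed by 0.15 (exact permutation p = 0.0260, adjusted p = 0.104) and that of 12 macrophage markers by 0.04 (exact permutation p = 0.504, adjusted p = 0.756). Transgenic 1 and transgenic 6 stood apart from the other arrays in principal components. Without both, 7 probes were higher, of which 4 belonged to the 11, and 73 were lower, of which 53 belonged to the 66. S100a9 had a value of 2.20 (limma adjusted p = 0.0588) and S100a8 1.69 (adjusted p = 0.155) in that fit, so neither passed. Mgl2 (adjusted p = 0.0561), Gadd45b (0.0642), Hcar2 (0.0715) and Cx3cr1 (0.106) lost their calls there as well. The neutrophil difference was then 0.78 (exact permutation p = 0.0143, adjusted p = 0.0857) and the fibroblast difference -0.64 (exact permutation p = 0.00476, the smallest possible with 210 assignments; adjusted p = 0.0571).

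With the neutrophil and the fibroblast marker means of each array as 2 terms in the limma fit, 1 higher and 3 lower probes passed. Cog2, Pebp1 and Col5a1 were the 3 lower ones, and the higher one was Gas6, a ligand of the receptor kinase Axl, at 1.83 (adjusted p = 0.0471), against 0.48 (unadjusted p = 0.0699) without these terms. In that fit S100a8 had a value of -0.78, S100a9 -0.09, Asprv1 -0.17, Hcar2 0.05, Pglyrp1 0.01 and Mgl2 0.37. Loxl1 had 0.03, Igfbp4 -0.24, Ltbp2 -0.51, Col1a1 -0.52, Col6a1 -0.63, Serpinf1 -0.77 and Serpinh1 -1.06, and none of these 13 passed (adjusted p of 0.391 or more). Of the 11 higher probes 8 kept their sign and 3 a change at least as large, with the median change going from 1.42 to 0.37 and the median SE from 0.21 to 0.35. Of the 56 lower probes above the noise limit on some array of each genotype, 53 kept their sign and 20 a change at least as large, with medians of -1.05 before and -0.76 after and of 0.18 and 0.32 for the SE. Retnlg, itself a neutrophil marker (1.23, SE 0.54), Cx3cr1 (0.75, SE 0.37), Gadd45b (0.77, SE 0.29), Relb (-2.04, SE 0.35), Dlg1 (1.57, SE 0.30) and Med30 (-1.45, SE 0.30) lost their calls mainly because the SE about doubled, since their changes stayed near or above the earlier ones. S100a8, S100a9, Pglyrp1 and Retnlg contribute to the neutrophil mean and Col1a1 and Col6a1 to the fibroblast mean. Their values in that fit are therefore partly fixed by construction. Both marker means follow the genotype label, which widens the SE of the genotype term.

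Of 27 gene lists fixed in advance, 24 had enough measured members to test, and 9 passed the camera test, 7 higher and 2 lower in animals labelled transgenic. With an estimated correlation only the neutrophil list passed, and with fry, which tests a set against no change, 5 did. Of 14 measured neutrophil markers 4 rose and 10 did not pass; 7 passed adjusted over the list alone (mean 0.84; camera adjusted p = 4.00e-11; adjusted p = 0.0160 with an estimated correlation). Lcn2 had a value of 1.17 (adjusted p = 0.102), Chil1 1.16 (adjusted p = 0.0707) and Csf3r, the receptor of granulocyte colony-stimulating factor, 0.60 (adjusted p = 0.109). Ltf and Camp, granule genes of maturing neutrophils, had values of 0.25 (adjusted p = 0.767) and 0.13 (adjusted p = 0.846). Of 12 S100 proteins and receptors, 2 rose, S100a8 and S100a9, both also adjusted over the list alone. The list mean was 0.44 and the median 0.14 (camera adjusted p = 0.00284, or 0.0556 with an estimated correlation). That mean rests largely on these 2 genes, which were named in advance as part of the study's field and are also neutrophil markers.

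Of 15 mesothelial and fibroblast markers 4 fell, 11 did not pass and 8 passed adjusted over the list alone (mean -0.67; camera adjusted p = 3.65e-10; adjusted p = 0.0772 with an estimated correlation). The members that fell were Col6a1, Col1a1, Col3a1, which was at least 1.48-fold lower, and Serping1, the C1 inhibitor, by 1.06 on the log2 scale (SE 0.21; adjusted p = 0.0209). Col3a1 lay below the noise limit on all 6 arrays labelled transgenic and above it on all 6 labelled nontransgenic. Serping1 lost its call without nontransgenic 2 (adjusted p = 0.0585), nontransgenic 5 (0.0552), transgenic 4 (0.0671) or transgenic 5 (0.0513), and also without the first set of 5 arrays described below (0.209) and with the marker means as terms (0.670). Col3a1 lost its call in those 2 fits (0.420 and 0.916) and without the 2 arrays that stand apart (0.0642). Serping1 and Col3a1 are members of the fibroblast marker mean, so the fit with marker means is partly fixed for them. Without the first set, Serping1 went from -1.06 to -1.07 and Col3a1 from -1.20 to -0.61. The mesothelial markers Msln, Krt7, Krt18, Upk3b and Krt8 had values of 0.10, -0.01, -0.03, -0.07 and -0.26 (adjusted p from 0.733 to 0.989), whereas Wt1 had -0.66 (adjusted p = 0.127) and passed adjusted over the list alone (0.00354).

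Antigen presentation and interferon lists passed without any member passing singly. For 13 genes of MHC class II presentation and co-stimulation the mean was 0.34 and 12 lay above 0 (camera adjusted p = 3.24e-05; adjusted p = 0.141 with an estimated correlation). H2-Eb1 had a value of 0.86 (SE 0.22; adjusted p = 0.0978), the single member that passed adjusted over the list alone, and Cd74, the class II invariant chain, 0.76 (SE 0.25; adjusted p = 0.311). For 27 interferon-stimulated genes the mean was 0.19 and 23 lay above 0 (camera adjusted p = 6.66e-04; adjusted p = 0.0556 with an estimated correlation), with 0 passing adjusted over the list alone. Igtp and Isg20 had values of 0.27 and 0.33 (adjusted p = 0.446 and 0.498). Neutrophil markers were higher on the same arrays, and the B cell marker mean differed by 0.15 (exact permutation p = 0.0260, adjusted p = 0.104).

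Of 12 genes of alternative macrophage activation, 1 rose, Mgl2, and 11 did not pass (mean 0.28; camera adjusted p = 0.00577; adjusted p = 0.0556 with an estimated correlation). With the marker means as terms the list mean was 0.13 (adjusted p = 0.884) and Mgl2 had 0.37 (adjusted p = 0.837), and neutrophil markers were higher on the same arrays (mean difference 0.84). Adjusted over the list alone, 5 passed higher, among them Retnla (0.80) and Arg1 (0.56), and 1 lower, Fcrls (-0.56). Of 24 apoptosis and survival genes 1 rose, Gadd45b, also adjusted over the list alone, and 23 did not pass (mean 0.15; camera adjusted p = 0.00381; adjusted p = 0.141 with an estimated correlation). Among 18 genes of the unfolded protein response 0 passed and 2 passed adjusted over the list alone (mean 0.15; camera adjusted p = 0.00933; adjusted p = 0.226 with an estimated correlation). These were Creld2, at 0.69 (adjusted p = 0.0623), and Hspa5, the chaperone BiP, at 0.52 (adjusted p = 0.101). That list lost its call without nontransgenic 4 (adjusted p = 0.0805), nontransgenic 6 (0.0503) or transgenic 3 (0.0517). Of 27 proliferation genes 0 passed and 21 lay below 0 (mean -0.17; camera adjusted p = 7.86e-04; adjusted p = 0.226 with an estimated correlation). Prc1, a mitotic spindle protein, had a value of -0.81 (adjusted p = 0.114) and alone passed adjusted over the list alone, and Plk1 had -0.37 (adjusted p = 0.261).

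Structure among the arrays bore on some of these lists. Without a first set of 5 arrays (2 transgenic, 3 nontransgenic) that stood on 1 side of the main component of variation within genotypes, 6 higher and 9 lower probes passed, and the MHC class II (adjusted p = 0.173), interferon (0.337) and proliferation (0.194) lists lost their calls. The median change of the same 56 lower probes went from -1.05 to -0.87, that of the 11 higher ones from 1.42 to 1.07. S100a9 went from 2.42 to 2.88, Asprv1 from 2.05 to 2.31, Cog2 from -1.72 to -1.88 and Med30 from -1.61 to -1.76, all of which passed, while Ltbp2 went from -1.51 to -0.79 (adjusted p = 0.346) and Col6a1 from -1.50 to -0.97 (0.538). Calls were also lost by Retnlg (0.410), Pglyrp1 (0.170), Mgl2 (0.170), Cx3cr1 (0.243), Gadd45b (0.533), Col1a1 (0.170), Serpinf1 (0.127), Loxl1 (0.137) and Igfbp4 (0.0658). Their changes in that fit were 1.07, 1.02, 0.92, 0.89, 0.52, -1.32, -1.10, -1.06 and -1.03, in the same order. Those of Mgl2 (0.86 before) and Cx3cr1 (0.78 before) were larger than with all animals, and the others were smaller. Only 4 transgenic and 3 nontransgenic animals remained, so a lost call need not mean a smaller change. The fibroblast marker difference went from -0.67 to -0.42 (exact permutation p = 0.0857). Without transgenic 1 and transgenic 6 the S100 list lost its call (adjusted p = 0.0841). With the marker means as terms, the MHC class II list (mean 0.59; adjusted p = 0.00448) and the proliferation list (mean -0.35; adjusted p = 0.00448) were the 2 that passed. The other 5 that could be tested had means of -0.05 (S100), 0.13 (alternative activation), -0.0034 (interferon), -0.09 (unfolded protein response) and 0.04 (apoptosis and survival), with adjusted p of 0.748 or more.

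**Figure D3:**
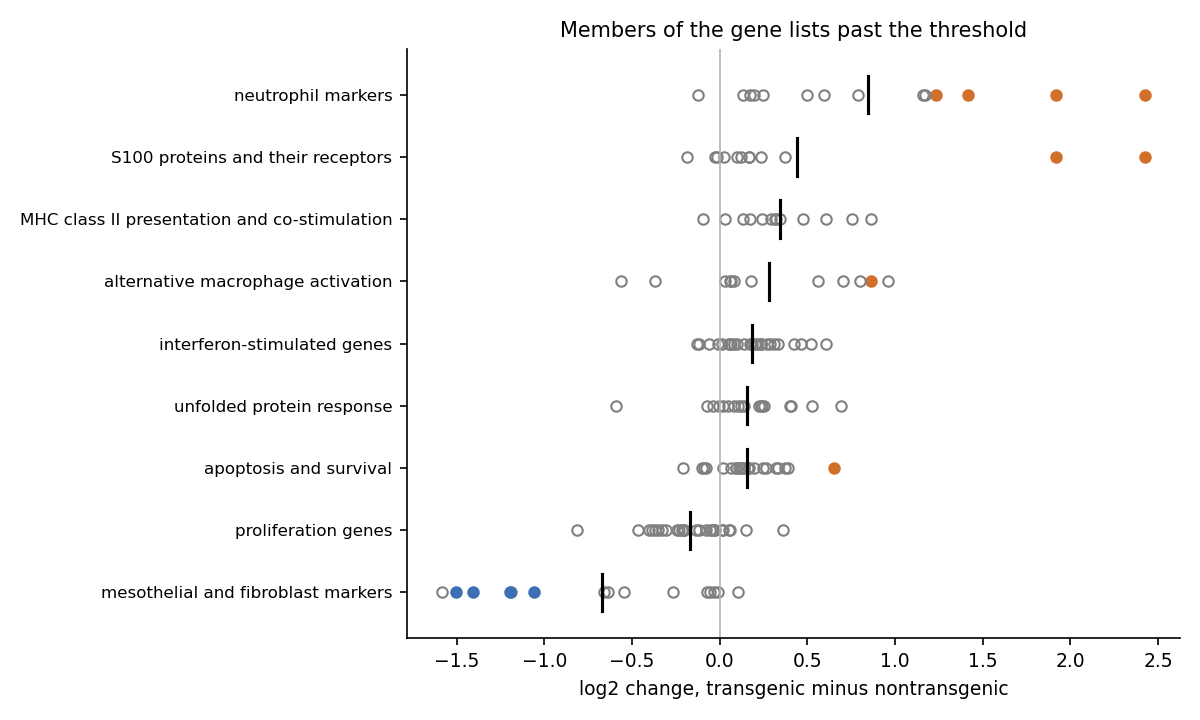
Log2 change of each measured member of the 9 gene lists that passed the camera test, labelled transgenic minus labelled nontransgenic, with filled points for genes that passed singly and a bar at the list mean. The neutrophil list averaged 0.84 and the mesothelial and fibroblast list -0.67, while the means of the other 7 lists lay between -0.17 and 0.44.

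The remaining lists did not pass. Among 27 matrix proteases and inhibitors, Mmp23 fell by 0.82 (SE 0.14; adjusted p = 0.00967) and Timp3, a tissue inhibitor of metalloproteinases, by 0.78 (SE 0.15; adjusted p = 0.0213), the same 2 adjusted over the list alone, and 25 did not pass (mean -0.03; camera adjusted p = 0.647). Timp3 lost its call in 5 fits that left out an animal, with adjusted p up to 0.0664 without nontransgenic 2. Without the first set of arrays Mmp23 had -0.50 and Timp3 -0.48 (adjusted p = 0.330 and 0.539), and with the marker means as terms they had -0.51 and -0.24 (adjusted p = 0.655 and 0.887). Fibroblast markers were lower on the same arrays. Among 25 growth factor and TGF-beta genes, 3 fell, Ltbp2, Vegfc by 0.88 (SE 0.19; adjusted p = 0.0386) and Egfr, at least 1.26-fold lower and below the noise limit on all 6 arrays labelled transgenic (adjusted p = 0.0191). Adjusted over the list alone 4 passed, the same 3 and Tgfb2 (list mean -0.12; camera adjusted p = 0.119). Vegfc lost its call in 8 of the 12 fits that left out an animal (adjusted p up to 0.119, without nontransgenic 2), and Egfr in 2, without nontransgenic 2 (0.0581) or transgenic 4 (0.0612). With the marker means as terms Vegfc had -0.16 and Ltbp2 -0.51 (adjusted p = 0.938 and 0.853), and without the first set -0.76 and -0.79 (adjusted p = 0.539 and 0.346). Egfr passed in neither (adjusted p = 0.432 and 0.429). Vegfc (adjusted p = 0.0721) and Egfr (0.0623) did not pass without the 2 arrays that stand apart. Fibroblast markers were lower here too.

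No gene of the lipid, oxidant or cytokine lists passed, either over all probes or adjusted over the list alone. In these diet-fed Apoe-/- mice the list means were -0.05 for 16 cholesterol efflux and LXR genes (camera adjusted p = 0.628) and -0.02 for 20 lipid uptake and foam cell genes (adjusted p = 0.689). For 16 cholesterol biosynthesis genes the mean was -0.01 and the median 0.01 (adjusted p = 0.993), so mean and median differed in sign. Lpl, lipoprotein lipase, had a value of 0.29, Scd2 -0.39, Lss -0.22, Fdft1 0.23, Gpnmb -0.22 and Pparg -0.30 (adjusted p of 0.546 or more), and 2 other Gpnmb probes had 0.06 and 0.09. For 31 inflammatory cytokines and chemokines the mean was 0.10 (adjusted p = 0.140), with Ccl24 at 0.96 (adjusted p = 0.132) and Il1b at 1.09 (adjusted p = 0.223). That list passed, higher, under 4 alternatives on the sets of arrays or the arrays that stand apart (adjusted p from 0.0137 to 0.0305) and without nontransgenic 1 (0.0269) or transgenic 6 (0.0154), and had a mean of -0.16 (adjusted p = 0.501) with the marker means as terms. For 27 NADPH oxidase and antioxidant genes it was 0.08 (adjusted p = 0.188), with Rac2 at 0.35 (adjusted p = 0.342) and Nfe2l2 at 0.30 (adjusted p = 0.446). For 21 hypoxia and glycolysis genes it was 0.06 (adjusted p = 0.214), with Slc16a3 at 0.27 and P4ha1 at 0.24 (adjusted p = 0.568 and 0.647). For 19 immediate early and dissociation genes the mean was -0.01, the median 0.04 and the test's direction upward (adjusted p = 0.689), with Dusp2 at 0.47 and Klf6 at 0.26 (unadjusted p = 0.00362 and 0.0305), neither of which passed after adjustment.

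Markers of the remaining cell types did not pass either. List means were 0.04 for 12 macrophage markers (camera adjusted p = 0.810), -0.15 for 19 markers of resident large peritoneal macrophages (adjusted p = 0.119), 0.15 for 8 B cell markers (adjusted p = 0.148) and 0.11 for 9 dendritic cell markers (adjusted p = 0.148). For 8 T and NK cell markers the mean was 0.04 although the test's direction was downward (adjusted p = 0.906). Gata6, the transcription factor of resident peritoneal macrophages, had a value of -0.87 (adjusted p = 0.296), Tgfb2 -0.38 (adjusted p = 0.291), Mertk 0.43 and Cd14 -0.23 (adjusted p = 0.635 and 0.720). The B cell genes Cd79b and Ebf1 had 0.76 and 0.40 (adjusted p = 0.205 and 0.498), the dendritic cell gene Fscn1 -0.90 (adjusted p = 0.0658), Cd2 -0.27 and Cd28 0.50 (adjusted p = 0.560 and 0.660), with -0.06 on a second Cd28 probe. Adjusted over the list alone, Cd79b passed, as did H2-Eb1 and Fscn1 among the dendritic cell markers. Only 4 mast cell and basophil markers and 4 erythroid and platelet markers could be measured, too few for a set test, with means of 0.09 and -0.03. Hdc, the histamine-forming enzyme, had a value of 0.94 (adjusted p = 0.243) and alone passed adjusted over the list alone, Cpa3 had -0.36, Pf4 -0.34 and Hbb-b2 0.08 (adjusted p from 0.697 to 0.911). None of 10 eosinophil markers on the array was bright enough to test.

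The pools asked whether the genotype differences held when the same RNA was mixed and hybridised again. Pools and animals share their RNA, so the pools are no independent evidence, and with 1 RNA per genotype there is no test. S100a9 differed by 2.00 on the log2 scale between the pools, against 2.42 between the animals, and Pebp1 by -1.89 against -1.63. Of the 77 probes past the threshold, 76 (98.7%) had the same sign in the pools, with a slope of 0.87 of pool on animal differences. Over all 10521 tested probes the correlation across probes was 0.41, and probes are not independent replicates. The median SD of repeat hybridisations was 0.17 on the log2 scale, against 0.24 between animals of 1 genotype, and for the 77 probes it was 0.18 against 0.35. Several named genes that did not pass differed in sign. Among them were Plaur, at 0.08 in the pools and -0.36 in the animals, Prc1 (0.42 and -0.81) and Lpl (-0.54 and 0.29).

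**Figure D4:**
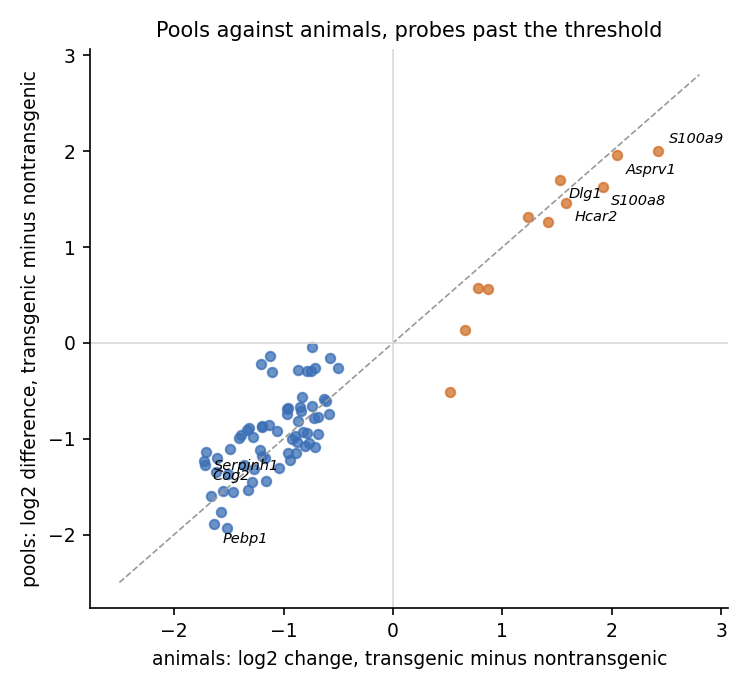
Log2 difference between the pools (vertical axis) against the log2 change between the animals (horizontal axis) for the 77 probes past the threshold, each labelled transgenic minus labelled nontransgenic. For 76 of them the sign was the same, and the slope was 0.87.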

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

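The tests of RNA from other cells, of the macrophage share, of the sets of arrays for the marker means, of the Plau probe, of the pools and of dim and bright probes under all splits were chosen only after the result was seen; the tests of wrong labels, of the sets for Plau, of linked genes, of the share of separated probes above noise and of chance division were set down before it.

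Within genotypes, 6 of 158 groups of 6 animals held a value far from the rest by Dixon's criterion, where chance would give about 7.9 (1 in 20). Hcar2 was high in nontransgenic 1 (gap 0.655 of the group's range), Retnlg in nontransgenic 4 (0.631) and Igfbp4 in nontransgenic 2 (0.744). Mmp23 was low in transgenic 1 (0.703), Igtp was high in transgenic 6 (0.882), and the macrophage marker mean was high in nontransgenic 4 (0.663).

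Neutrophil markers were higher and mesothelial and fibroblast markers lower in animals labelled transgenic. A lower macrophage share that left the proportions of the other cells unchanged would raise both. They moved apart by 1.52 on the log2 scale, which argues against that form alone. A share taken up by neutrophils need not raise stromal RNA, and the opposite movement is the pattern itself, so it cannot decide on that form. The macrophage marker mean differed by 0.04 (exact permutation p = 0.504). The sets of arrays are argued against as the whole source, since both marker means kept an exact p of 0.00286 with genotype permuted within the sets (350 assignments, differences 0.91 and -0.67) and of 0.00446 with the tighter split. The sets bear on its size, though: without the first set the neutrophil difference was 0.90 (exact p = 0.0286, the smallest possible) and the fibroblast difference only -0.42 (exact p = 0.0857). They were also drawn from deviations within genotypes, so they hold similar shares of both by design and would miss a batch that follows genotype. RNA of neutrophils among the adherent cells, and fewer fibroblasts, cannot be told apart from a difference in expression within macrophages, the biological explanation that the genotype offers. The 10 neutrophil markers that did not pass singly differed by 0.48 as a set and the 11 other stromal markers by -0.45, with members from Lcn2 (1.17) to Anxa1 (-0.13) and from Dcn (-1.58) to Msln (0.10), but these are members of the lists that showed the pattern, so they neither support nor exclude it, and S100a8 and S100a9 belong to the neutrophil list.

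Plau was not higher in animals labelled transgenic. Wrong labels for 1 animal or an exchanged pair are argued against only if the called probes follow genotype, which Plau could not show. The labels as given called 77 probes and the 48 changed labellings at most 42, but an exchange of all labels would leave that count the same. With the sets of arrays as a term the difference was -0.052 (95% interval -0.96 to 0.85), so no increase of 1 log2 unit or more appeared. The sets hold similar shares of both genotypes by design, so such a term could move the difference little and would miss a batch that follows genotype. With only 1 Plau probe, a probe outside the part of the transcript that the transgene carries cannot be told apart from absent overexpression. No biological explanation was tested.

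For 113 probes the genotypes did not overlap, among them Pebp1, Med30, Cog2 and Relb, which belong to none of the cell type lists. Linked stretches of another strain's genome are argued against as the main source of these probes as a whole, not for any single gene. There were 8 pairs of such genes within 10 tested genes of each other, where random draws gave a median of 10. That count over all chromosomes could not show 1 stretch, whether beside the transgene, beside the disrupted Apoe gene that all mice carry, or elsewhere. The distance of the separated genes from Apoe was not examined. On chromosome 8, Rpl13 and Tubb3 lay 7 tested genes apart and Tubb3 and Cog2 10 (log2 changes -0.50, 0.40 and -1.72). A single stretch stays open, as do scattered variants under single probes, which the opposed Dlg1 probes could have (1.53 and -0.09). That 91.2% (103) were above the noise limit on all 6 arrays of the brighter group decides nothing about noise of dim probes, since 78.3% of all tested probes were. Noise alone is argued against by all 462 splits: 9 with the real one separated as many of the probes above the limit on all 12 arrays as the 64 that genotype did (mean 16.2), and only the real 1 as many of the others, 49 (mean 6.34, highest other 23). Another split separated 103 of the brighter probes, which points to structure among the arrays beside genotype. Errors of single hybridisations are argued against for the 61 that passed the limma test, 98.4% of which differed the same way in the pools, but not for the other 52, of which 57.7% did. An effect of the transgene on these genes remains a hypothesis.

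Chance division of the animals was tested with 100 of the 462 splits, the real one included. Only the real split, 1 of 100, gave as many as 77 probes in all (highest other 1), 11 higher (highest other 1) or 66 lower (highest other 1), and 1 of 100 gave as many as 9 lists, where the highest other split gave 8. Chance is argued against for the probe counts, as far as 100 splits can show. It stays open for the list count, since 9 lies close to 8 and the other splits were not run.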

How the results depend on the processing

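The tests with the sets of arrays, the arrays left out as sets or pairs, the title number, the marker means, the larger constant, the raised dim values and no further normalization were chosen only after the result was seen. Signal over noise limits the dim probes, and the smaller counts follow in part from construction where fewer animals or more probes entered. Plau passed under none of the 20 alternatives (log2 difference -0.91 to -0.05), and the neutrophil list passed under all 21 that could be run. Without each animal in turn, 6 to 15 probes were higher and 34 to 78 lower, 8 to 11 lists passed and 2 to 3 marker checks did, and Plau ranged from -0.39 to 0.15. No filter on dim probes gave 7 higher and 35 lower probes, and probes above noise on all 12 arrays gave 5 and 28. The exact Mann-Whitney test gave 0 and 0 (413 higher and 370 lower at an unadjusted p under 0.05), since the 113 probes at its smallest p have an adjusted p of 0.202 and too few probes tie there to pass. The set of arrays as a term gave 30 higher probes, including the same 11, and the set of 4 gave 23, including 9 of them; the cause was not tested. Without the first set, which leaves 4 transgenic and 3 nontransgenic animals, 6 higher and 9 lower probes passed (5 and 8 shared) and 0 marker checks, whose smallest p is then 0.0286. Without the 2 arrays that stand apart, 7 probes were higher and 0 checks passed. Marker means as terms gave 1 higher and 3 lower probes and 2 lists. Camera with an estimated correlation gave 1 list and fry 5.

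With the marker means as terms signs turned for S100a8 (-0.78), S100a9 (-0.091), Asprv1 (-0.17), Loxl1 (0.028), Il1b (-0.47), Scd2 (0.52), Pparg (0.38), Isg20 (-8.40e-05), Klf6 (-0.0074), Cd14 (0.0072), Hdc (-0.23) and Hbb-b2 (-0.31). So did the list means of S100 (-0.047), cytokines (-0.16), cholesterol efflux (0.18), lipid uptake (0.067), oxidants (-0.033), unfolded protein (-0.088) and interferon (-0.0034), the last without a turn in camera's direction, which compares members with all other genes. For T and NK cells (0.0036) only that direction turned. S100a8, S100a9 and some list members are part of those means, and the 2 marker lists were not tested there because their means are then 0 by construction. For the others the cause was not tested.

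For other lists the direction given by the set test turned, and the cause was not tested. The mean changed sign too for cholesterol biosynthesis with the set as a term (0.0080), the set of 4 (0.018) and without the first set (0.081), for matrix proteases with probes above noise on all arrays (0.010) and without the first set (0.0065), for growth factors above noise on all arrays (0.091), and for lipid uptake without the first set (0.029) and without 2 arrays (0.0066). The mean kept its sign, and only the direction turned, for cholesterol biosynthesis under cyclic loess (-0.014), the title number (-0.0043) and fry (-0.0059), for T and NK cells under array weights (0.053), the set (0.049) and without 2 arrays (0.094), for immediate early genes without a filter (-0.042), and for macrophage markers with the set of 4 (0.0050). The mean alone changed sign for T and NK cells without the first set (-0.081) and, several times, for immediate early genes, whose mean lies near 0 and reached 0.32 with the marker means as terms. Without each animal in turn, list means ranged from -0.048 to 0.020 for cholesterol biosynthesis, 0.0021 to 0.12 for T and NK cells, 0.016 to 0.081 for macrophage markers and -0.059 to 0.031 for immediate early genes.

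Some lists passed only under alternatives. The cytokine list did so with the set as a term (adjusted p = 0.0249), the set of 4 (0.0137), without the first set (0.0305), without 2 arrays (0.0269), without nontransgenic 1 (0.0269) and without transgenic 6 (0.0154). Resident macrophage markers did with the set of 4 (0.0365) and without transgenic 6 (0.0128), dendritic cell markers with probes above noise on all arrays (0.0170), growth factors without transgenic 3 (0.0472), and plasminogen activation (0.0491) and hypoxia (0.0499) without 2 arrays. Among the named genes Creld2, Fscn1, H2-Eb1, Prc1, Gata6 and Hdc passed under some alternatives.

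Pool repeats share only a number, so the pairing is no block of the design: the S100a9 pool difference was 2.16 for pair 1 and 1.84 for pair 2, with no test. The deposited table is the source of the values and so was not run as an alternative, and chip and array position were not run because the sources do not tie them to arrays.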

Other observations

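Genes past the threshold that the rule for named genes left out were described after their values were seen. Genes picked among them for their known functions, with no test of a group, were lower in animals labelled transgenic, as were 66 of the 77 probes past the threshold: Col18a1 (-1.28, limma adjusted p = 0.0140), the proteoglycan perlecan gene Hspg2 (-1.16, adjusted p = 0.0126), Fbln2 (-1.17, adjusted p = 0.0399), Ccdc80 (-1.34, adjusted p = 0.0399) and Spon2 (-1.32, adjusted p = 0.0388). The alarmin gene Il33 (-0.85, adjusted p = 0.00612) and the oncostatin M receptor gene Osmr (-0.89, adjusted p = 0.0366) were lower too. Fibroblast markers were lower on the same arrays. Tef, a clock-output transcription factor, was lower by a log2 change of -1.28 (adjusted p = 1.94e-04), and so were Ddah2 (-0.87, adjusted p = 7.05e-04), G3bp1 (-0.94, adjusted p = 0.00215) and the ribosomal protein gene Rpl13 (-0.50, adjusted p = 0.0229).

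In both genotypes some probes read outside the range of the animals that made up the pool. Both repeats lay above all 6 animals for 40 probes and below them for 51, and the deviations of the pools correlated at 0.34 across probes, which are not independent replicates. Nr1d2, a clock gene, was lower in the pools by log2 differences of -0.64 (transgenic) and -0.75 (nontransgenic) from the mean intensity of the animals, and Exo5 was higher by 0.62 and 0.63.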
